A study of Mus musculus with 48 samples.

How the data were processed

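Expression was measured in 48 mouse samples, 1 Affymetrix MG-U74Av2 array each, from liver, heart, spleen and lung of the inbred strains A/J and C57BL/6J. Each tissue of each strain was sampled at 2 time points, called time 1 and time 2, whose meaning is not given in the sources used here. Per the labels, each of the 16 groups holds 3 biological replicates, which were male littermates aged 3 months, and targets were made from about 20 micrograms of total RNA. The sources do not say whether a mouse gave more than 1 tissue, or how many litters were used. The p-values therefore measure the spread between these animals, and a difference between litters cannot be separated from a difference between groups.

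The deposited values are on a log2 scale, for 12488 probe sets (sets of short probes that each read 1 or more transcripts), and range from 4.252 to 14.72. The authors made the arrays comparable by a method that is not given in the sources used here. The array medians lie between 8.863 and 9.01, and the sorted values are not identical between arrays. The values were used as deposited, with no floor and no filter on low values. For arrays, the number of samples limits the precision, and a signal near the background cannot be told from absence, so that a difference from it is a lower bound. In the 18 arrays of liver, lung and spleen at time 1, 4 to 21 probe sets shared the highest value of the array (14.31 to 14.40), a ceiling at which differences are lower bounds.

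The 66 control probe sets were left out, which left 12422. Gene names came from the platform's probe table. It gave 1 gene symbol for 10833 of these probe sets and several for 396, and 1193 were not listed. Of the probe sets with 1 symbol, 10817 had an Entrez identifier found in the mouse gene table, and together they name 8251 genes. Only probe sets with 1 symbol are named in the text. Whether such a set also reads related transcripts was not checked. The mouse gene models of assembly GRCm38.p6 were used only to find which genes neighbour each other.

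The file names of the scanned arrays fall into 4 sets, called array runs here. Liver and lung at time 1 share 1 run, spleen at time 1 and heart at time 1 each have their own, and all tissues at time 2 share the last. Both strains share a run within each tissue and time, so strain comparisons lie within runs. A comparison of times within a tissue is also a comparison of runs, and the 2 cannot be told apart.

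Tests used limma 3.58.1 in R 4.3.3, with the Benjamini-Hochberg adjustment over all 12422 probe sets and a limit of 0.05 on the adjusted p. Strain (A/J minus C57BL/6J) was tested in the 12 arrays of each tissue with time as an additive term, and time (time 2 minus time 1) with strain as an additive term. The strain by time test asked whether the strain difference at time 2 departed from that at time 1. The strain by tissue test was an F test over all 48 arrays with a mean for each tissue and time. A probe set was called enriched in a tissue when its mean exceeded that of each other tissue by at least 1 log2 unit with an adjusted p below 0.05 in all 3 contrasts. Differences are given on the log2 scale with the standard error (SE) of the fit, and group means with the standard deviation (SD).

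For each tissue, 37 lists of cell type markers and pathway genes were tested for strain and for time with camera (preset correlation between genes of 0.01, adjusted over the lists of a comparison). Each gene was read by its probe set with the highest mean over all arrays. The tests were repeated with an estimated correlation, with fry, and with the mean over all probe sets of each gene. The comparisons, the tests, the lists, the alternatives and the rule for named genes were set before the data were examined.

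The rule named, in each tissue, the 8 genes with the largest strain difference in each direction among those past the test, with 1 symbol and with the same sign at both times. It added the 8 genes per direction called in all 4 tissues with the largest mean difference, a short list of genes with known alleles in these strains, and up to 4 members of each other list with the smallest p. For strain by tissue it named the 12 genes with the smallest p, for each tissue the 8 enriched genes with the largest smallest-of-3 difference, for time 6 genes per direction and tissue, and for strain by time the 4 with the smallest p per tissue. Where a gene had several probe sets, the others were read as well for strain.

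The calculations were tested on simulated data, with 200 of 12422 probe sets changed. Normal noise was drawn independently for each probe set, with 1 SD pooled over all groups. It held no correlation between genes and no spread particular to a tissue. Strain differences of 1 log2 unit were recovered in 99% to 100% of cases and those of 0.5 in 93% to 96%. Strain by time differences of 1 were recovered in 90% to 92% and those of 0.5 in 19% to 27%. The highest share of false calls was 6.73%. These shares test the calculations and need not hold for the real arrays.

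Alternatives were quantile normalization, array weights, a variance trend with intensity, a replicate block, leaving out the 4141 dimmest probe sets, other model terms, each time alone, all 48 arrays in 1 fit, stricter limits, and leaving out each array. Floors for linear signals do not apply to log values and were not run. Alternatives chosen after seeing the data left out 5 spleen arrays with high pancreas transcripts, 2 heart arrays with a high 3' end of the Gapdh control (the lone array left in that group is assumed to vary like the other groups), or probe sets typical of another tissue.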

Results

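RNA of liver, heart, spleen and lung was measured on 48 arrays, 3 in each of 16 groups formed by tissue, strain (A/J or C57BL/6J) and time (1 or 2). A/J and C57BL/6J are inbred mouse strains that differ at many known loci. The titles of the samples name tissue, strain and time, and no aim of the study is stated, so the comparisons below are those that the grouping itself poses. Array medians lay between 8.863 and 9.01 on the log2 scale. The replicate SD around the group means was larger in spleen at time 2, at a mean of 0.1591 over 6 arrays, than in heart at time 1, at 0.1018 over 6 arrays.

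In liver, the strain comparison asked which transcripts differed between A/J and C57BL/6J. Cyp2c39, a cytochrome P450, was 6.37-fold higher in A/J (12.97 ± 0.16 against 10.30 ± 0.09, log2 mean ± SD, n = 6 per strain). Nnmt, which methylates nicotinamide, was 5.72-fold higher in C57BL/6J (11.11 ± 0.17 against 8.59 ± 0.09, n = 6). Fga, the alpha chain of fibrinogen, was 5.91-fold higher in C57BL/6J (13.16 ± 0.32 against 10.60 ± 0.15, n = 6), and Hc, which encodes complement C5 and is known to be defective in A/J, was 4.54-fold higher there (12.49 ± 0.14 against 10.30 ± 0.29, n = 6). Asl, an enzyme of the urea cycle, was 2.73 log2 units higher in C57BL/6J (SE 0.23), while another probe set of the gene gave 0.08 for A/J minus C57BL/6J. Other large differences were Gas5, a non-coding host of small nucleolar RNAs (3.02 higher in C57BL/6J, SE 0.15), Psen2, a presenilin (1.94, SE 0.13), Ctsc, the protease cathepsin C (1.85, SE 0.13), and Qsox1, a sulfhydryl oxidase (1.82, SE 0.05), whose other probe sets gave 0.05 and -0.39 for A/J minus C57BL/6J, the latter called. Higher in A/J were Apcs, serum amyloid P (1.66, SE 0.18), Hbb-b2, a beta globin (1.44, SE 0.11), Snrnp25 (1.302, SE 0.07), Asic5 (1.25, SE 0.18), Ccl9, a chemokine (1.24, SE 0.14), and Glo1, glyoxalase 1 (1.24, SE 0.09). Cyp2b9, another cytochrome P450, was higher in A/J by at least 0.60 at time 1 and at least 3.38 at time 2, since the C57BL/6J livers (7.84 to 8.11) lay within the 7.54 to 8.38 of the other tissues.

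By list, liver macrophage markers were lower in A/J in 3 of 14 measured genes and 5 adjusted over the list alone, among them Cd5l (-0.76), C1qb (-0.51) and C1qc (-0.40), although another probe set of C1qb gave 0.29 and did not pass. The list's adjusted p was 4.8e-05, and adjusted p = 0.808 with an estimated correlation. Of 22 interferon response genes, 6 were lower in A/J and 9 adjusted over the list alone, such as Rsad2 (-0.56), Ifi27 (-0.47) and Irf9 (-0.34), with an adjusted p of 1.77e-06 and adjusted p = 0.808 with an estimated correlation. MHC and antigen processing genes were lower in 3 of 20 (4 adjusted over the list alone), among them H2-Q10 (-0.39) and H2-Eb1 (-0.38), with adjusted p = 0.0378 and adjusted p = 0.808 with an estimated correlation. Of 22 cytochrome P450 genes, 5 were higher in A/J and 1 lower (7 and 1 adjusted over the list alone), with Cyp2c29 at 0.76 and Cyp3a13 at -1.68, adjusted p = 0.00616 and adjusted p = 0.539 with an estimated correlation. Cholesterol synthesis genes were higher in 2 of 17 and lower in 1 (the same adjusted over the list alone), with Sc5d at 0.54, Hmgcs1 at 0.47 and Ebp at -0.25. That list had adjusted p = 0.0161 and adjusted p = 0.808 with an estimated correlation, and another probe set of Sc5d gave -0.47 and did not pass. Oxidative phosphorylation genes were lower in 2 of 57 (3 adjusted over the list alone), Ndufa6 at -0.42 and Ndufb10 at -0.31 (another probe set of the latter -0.03), with adjusted p = 0.0238 and adjusted p = 0.808 with an estimated correlation. Of 19 heat shock genes 1 was lower, Hspb8 at -0.40 (2 adjusted over the list alone), with adjusted p = 0.00616 and adjusted p = 0.808 with an estimated correlation. The median A/J minus C57BL/6J difference had opposite signs at time 1 and time 2 for MHC and antigen processing (-0.23 and 0.15), cholesterol synthesis (-0.026 and 0.28), oxidative phosphorylation (0.018 and -0.11) and heat shock (0.095 and -0.24). For interferon response it was -0.25 and -0.09. With the mean over all probe sets of each gene, MHC and antigen processing (adjusted p = 0.233), cholesterol synthesis (0.0924) and oxidative phosphorylation (0.15) no longer passed. Complement and coagulation genes were lower in 5 of 25 (5 adjusted over the list alone), including F12 (-0.85), Pros1 (-0.69) and C9 (-0.60), but the list did not pass (adjusted p = 0.152). Its median was 0.01 while its mean was -0.16. In all, 505 liver probe sets passed for strain, 191 higher in A/J and 314 higher in C57BL/6J, and 37 of them differed at least 2-fold. That balance depended on time, since 201 were higher in A/J and 143 in C57BL/6J with time 1 alone, and 433 and 827 with time 2 alone. All 505 had the same sign at both times, which the test favours, since a difference that turns between the times is hard to call. Over all probe sets, called or not, the differences at the 2 times correlated at 0.187.

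In heart, Baiap2l1, a protein that binds membranes and actin, was 3.85-fold higher in A/J (10.97 ± 0.19 against 9.03 ± 0.08, n = 6 per strain). Myl1, a myosin light chain, was 2.55-fold higher in A/J (11.23 ± 0.17 against 9.88 ± 0.23, n = 6), as were Acta1, skeletal actin, 2.12-fold (14.29 ± 0.03 against 13.21 ± 0.59, n = 6), and Acta2, smooth muscle actin, 2.04-fold (11.96 ± 0.40 against 10.93 ± 0.24, n = 6). Hopx, a homeodomain-only protein of heart muscle, was 3.44-fold higher in C57BL/6J (12.31 ± 0.07 against 10.53 ± 0.12, n = 6). Glo1 (1.63, SE 0.04), Ift81 (1.53, SE 0.05, and 0.52 without passing in another probe set), Alad, an enzyme of heme synthesis (1.195, SE 0.05), and Kpna2, an importin (0.99, SE 0.12), were also higher in A/J. Higher in C57BL/6J were Gas5 (2.75, SE 0.08), Clip4 (2.26, SE 0.16), Cyfip2 (1.97, SE 0.07), Snhg6 (1.96, SE 0.09), Bpgm, the red cell bisphosphoglycerate mutase (1.77, SE 0.33), Rgs5, a regulator of G protein signalling (1.62, SE 0.11), and Pttg1, securin (1.54, SE 0.06), while another probe set of Pttg1 gave -0.17 for A/J minus C57BL/6J and did not pass. The lists of cardiomyocyte, skeletal muscle and smooth muscle markers did not pass (adjusted p = 0.369, 0.611 and 0.0758, the last 0.042 without 2 A/J hearts of time 1 with a high Gapdh 3' end).

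The heart showed lower antigen presentation transcripts in A/J. Of 20 MHC and antigen processing genes, 6 were lower in A/J (9 lower and 1 higher adjusted over the list alone), among them Cd74 (-1.28), H2-Aa (-0.95), B2m (-0.73) and H2-Eb1 (-0.65), with adjusted p = 8.96e-06 and adjusted p = 0.443 with an estimated correlation. The median difference of this list was -0.32 at time 1 and -0.06 at time 2, and that of the interferon list -0.25 and -0.05. Of 22 interferon response genes 5 were lower (7 adjusted over the list alone), led by Rsad2 (-1.34), Ifit3 (-0.37) and Isg15 (-0.34), with adjusted p = 4.3e-06 and adjusted p = 0.347 with an estimated correlation. Macrophage markers were lower in 5 of 14 (7 adjusted over the list alone), including C1qb (-0.67), C1qc (-0.56) and Mpeg1 (-0.34), where other probe sets of C1qb and Mpeg1 gave -0.07 and -0.07, with adjusted p = 1.19e-05 and adjusted p = 0.238 with an estimated correlation. Erythroid markers were lower in 2 of 9 (5 adjusted over the list alone), Alas2 at -1.38 and Rhd at -0.36, with adjusted p = 1.36e-04 and adjusted p = 0.349 with an estimated correlation. Lung epithelium markers were lower in 2 of 9 in the A/J hearts (6 adjusted over the list alone), Hopx and Ager (-0.25), with adjusted p = 8.96e-06 and adjusted p = 0.238 with an estimated correlation. Hopx is also a gene of heart muscle and was lower in A/J in every tissue, so it does not mark lung here. In the hearts at time 1, Scgb1a1, a secretory protein of airway cells, stood at 10.67 ± 0.94 in A/J and 13.01 ± 0.98 in C57BL/6J (n = 3). Oxidative phosphorylation genes were higher in 3 of 57 (3 adjusted over the list alone), Ndufa8 at 0.43, Sdhd at 0.21 and Ndufc1 at 0.18, with adjusted p = 1.98e-04 and adjusted p = 0.443 with an estimated correlation. In all, 929 heart probe sets passed, 568 higher in A/J and 361 higher in C57BL/6J, with 27 at least 2-fold. With time 1 alone 288 and 150 passed, and with time 2 alone 245 and 255. All 929 had the same sign at both times, which the test favours, and over all probe sets the differences at the 2 times correlated at 0.477. The Gapdh control, a sign of RNA integrity, was higher at its 3' end than at its 5' end by 0.95 ± 0.73 in the A/J hearts at time 1 and by 0.096 to 0.26 in the other heart groups (n = 3), and without the 2 highest of these arrays, an alternative chosen after seeing the data, 845 passed, 655 of them shared in the same direction.

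In spleen, transcripts of red cell precursors were higher in A/J. Hemgn, a nuclear protein of erythroid cells, was higher by 1.34 log2 units at time 1 and by 5.03 at time 2 (11.78 ± 0.64 against 8.59 ± 1.73 over both, n = 6 per strain). Of its C57BL/6J arrays 1 stood at 6.04, within the 5.77 to 6.40 of the other tissues, so the difference at time 2 is a lower bound. Likewise higher were Alad 8.33-fold (13.40 ± 0.23 against 10.34 ± 0.69, n = 6), Epb42, a protein of the red cell membrane, by 1.295 at time 1 and 3.62 at time 2 (9.42 ± 0.59 against 6.96 ± 1.03, n = 6), and Rhag, the Rh associated glycoprotein, 4.72-fold (12.38 ± 0.30 against 10.14 ± 1.01, n = 6). In the other direction, Ighv14-2, a variable segment of antibody heavy chains, was 16.5-fold higher in C57BL/6J (12.07 ± 0.22 against 8.02 ± 0.08, n = 6), and Ly6d, a surface protein of B cells, 4.73-fold (13.07 ± 0.33 against 10.83 ± 0.20, n = 6). Aqp1, the water channel of red cells (2.38, SE 0.33), Ctse, cathepsin E (2.31, SE 0.41), Sowaha (2.28, SE 0.29) and Mki67, a marker of dividing cells (2.24, SE 0.39), were higher in A/J. Other probe sets differed: that of Aqp1 gave 0.02, that of Epb42 0.09, that of Mki67 0.01, and those of Ctse -0.72 and -0.52, both called. Higher in C57BL/6J were Gas5 (3.47, SE 0.17), Cd5l, a product of macrophages (2.46, SE 0.16), Ctsc (2.14, SE 0.11), Ighg3 (1.91, SE 0.33), Spg21 (1.84, SE 0.14) and Snhg6 (1.80, SE 0.13). Here too other probe sets differed. For Ighg3, 1 was called in the opposite direction at 0.67, while -1.39 and -1.25 passed and -0.35, -0.20 and -0.40 did not. Those of Ighv14-2 gave -0.60, which passed, and 0.07, and that of Ly6d -0.21 without passing.

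Of 9 erythroid markers 7 were higher in the A/J spleens (7 adjusted over the list alone), with Rhd at 1.94, Slc4a1 at 1.79, Klf1 at 1.64 and Fech at 1.15, adjusted p = 2.28e-06 and adjusted p = 0.304 with an estimated correlation. Their median difference was 0.48 at time 1 and 1.82 at time 2. Of 38 cell cycle genes 28 were higher and 2 lower (30 and 2 adjusted over the list alone), with Ccnb2 at 1.42 and Lig1 at 0.76 against Ccnd2 at -0.91 and Ccnd1 at -0.61. That list had adjusted p = 9.93e-14 and adjusted p = 0.358 with an estimated correlation, and a median difference of 0.32 at time 1 and 1.09 at time 2. Neutrophil markers were higher in 6 of 12 and lower in 1 (9 and 1 adjusted over the list alone), such as Ngp (1.01), Mpo (0.80) and Ltf (0.49), with adjusted p = 2.4e-04 and adjusted p = 0.552 with an estimated correlation. NK cell markers were lower in 5 of 9 (6 lower and 1 higher adjusted over the list alone), with Ccl5 at -1.24, Klrd1 at -1.16 and Gzma at -0.66, adjusted p = 1.31e-04 and adjusted p = 0.0646 with an estimated correlation. Macrophage markers were lower in 6 of 14 (8 lower and 1 higher adjusted over the list alone), with Mpeg1 at -1.57, Marco at -1.36 and Lyz2 at -0.70, adjusted p = 1.31e-04 and adjusted p = 0.304 with an estimated correlation. B cell markers were lower in 5 of 13 (7 adjusted over the list alone), with Cd79a at -0.83, Cd22 at -0.59 and Ly86 at -0.54, adjusted p = 0.00509 and adjusted p = 0.368 with an estimated correlation. MHC and antigen processing genes were lower in 10 of 20 and higher in 1 (12 and 1 adjusted over the list alone), with Tap1 at -1.17, H2-Ab1 at -1.11 and H2-DMb1 at -0.64 against H2-Ea at 1.04, adjusted p = 3.57e-09 and adjusted p = 0.0646 with an estimated correlation. Interferon response genes were lower in 6 of 22 and higher in 2 (9 and 2 adjusted over the list alone), with Ifi30 at -0.67 and Mx1 at -0.51 against Igtp at 0.58, adjusted p = 0.00618 and adjusted p = 0.642 with an estimated correlation. Their median difference was -0.42 at time 1 and -0.028 at time 2. Other probe sets of genes in these lists did not pass, at 0.11 for Lig1, -0.20 for Ccnd1, 0.19 for Mpo, -0.01 for Mpeg1, 0.15 for Lyz2 and 0.10 for Tap1.

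Liver transcripts were also higher in the A/J spleens. Of 15 hepatocyte markers 3 were higher, Fgg (0.63), Fga (0.50) and Fgb (0.49), and 11 adjusted over the list alone, with adjusted p = 2.63e-05 and adjusted p = 0.552 with an estimated correlation. The median difference of these markers was 0.14 at time 1 and 0.70 at time 2. Acute phase genes were higher in 3 of 21 and lower in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0189, and adjusted p = 0.642 with an estimated correlation), and cytochrome P450 genes higher in 4 of 22 and lower in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.00208, and adjusted p = 0.586 with an estimated correlation). Alb, the albumin of liver cells, stood at 12.52 ± 0.69 in the A/J spleens at time 2 and between 8.74 and 9.07 in the other 3 spleen groups (n = 3). In all, 1580 spleen probe sets passed for strain, 751 higher in A/J and 829 higher in C57BL/6J, and 167 differed at least 2-fold, 111 of them higher in A/J. With time 1 alone 233 and 370 passed in the same order, and with time 2 alone 663 and 445. All 1580 had the same sign at both times, which the test favours, and over all probe sets the differences at the 2 times correlated at 0.452. Markers of the exocrine pancreas, an organ beside the spleen, reached means of 12.08 to 13.18 in 5 of the 12 spleen arrays and 9.33 to 10.06 in the others. Without those 5 arrays, an alternative chosen after seeing the data, 358 probe sets passed, 348 of them shared in the same direction. Leaving out other sets of 5 arrays of the same layout gave a median of 322.

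**Figure D1:**
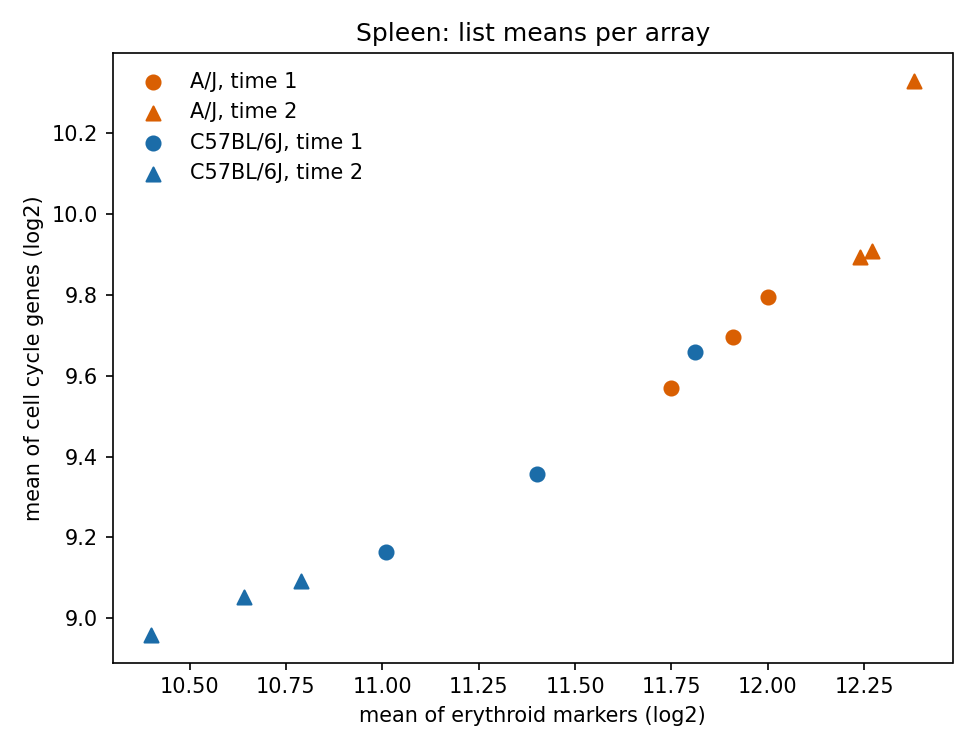
Mean log2 level of the erythroid markers (horizontal) and of the cell cycle genes (vertical) in each of the 12 spleen arrays, by strain (colour) and time (shape). The A/J and C57BL/6J group means were 11.88 and 11.40 (erythroid) and 9.69 and 9.39 (cell cycle) at time 1, and 12.30 and 10.61, and 10.04 and 9.03, at time 2.

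In lung, Ifi204, an interferon-induced gene, was 6.38-fold higher in A/J (10.71 ± 0.32 against 8.04 ± 0.23, n = 6 per strain), with other probe sets of the gene at 0.62 and -0.02 for A/J minus C57BL/6J. The C57BL/6J lungs stood no higher than the other tissues (8.10 to 8.96), so the fold is a lower bound. A probe set of Igha, the heavy chain of IgA, was 3.77-fold higher in A/J (11.15 ± 0.50 against 9.23 ± 0.24, n = 6), while its other probe sets gave 0.30 and -0.10 and did not pass. A probe set of Ighm, that of IgM, was 3.64-fold higher (11.25 ± 0.82 against 9.38 ± 0.16, n = 6), and of 15 others, between -0.10 and 0.38, only the highest passed. Chil3, a chitinase-like protein of macrophages, was 3.06-fold higher in C57BL/6J (12.76 ± 0.36 against 11.15 ± 0.39, n = 6). Baiap2l1 (1.86, SE 0.05), Glo1 (1.79, SE 0.09), H2-D1, an MHC class I gene (1.76, SE 0.12), Gbp2b, a guanylate binding protein (1.65, SE 0.14), and Gnb1, a G protein subunit (1.45, SE 0.07), were also higher in A/J. Higher in C57BL/6J were Gas5 (2.96, SE 0.16), Ctsc (2.53, SE 0.15), Ighv14-2 (1.59, SE 0.33, with other probe sets at 0.06 and 0.45 for A/J minus C57BL/6J, neither past the test), Cxcl14, a chemokine (1.39, SE 0.14), Snhg6 (1.38, SE 0.06), Sox11 (1.24, SE 0.10) and Spg21 (1.19, SE 0.14).

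Neutrophil markers were lower in the A/J lungs in 4 of 12 genes (6 adjusted over the list alone), with Ngp at -0.72, Camp at -0.58 and Ltf at -0.38, adjusted p = 0.00106 and adjusted p = 0.408 with an estimated correlation. Platelet markers were lower in 3 of 4 (3 adjusted over the list alone), Gp1bb at -0.53, Gp9 at -0.40 and Gp5 at -0.31 (another probe set of Gp5 -0.11), with adjusted p = 0.00314 and adjusted p = 0.241 with an estimated correlation. NK cell markers were lower in 2 of 9 (4 adjusted over the list alone), Gzma at -0.50 and Klrd1 at -0.35, with adjusted p = 0.0161 and adjusted p = 0.484 with an estimated correlation. Endothelial markers went both ways, with Tek at 0.44, Kdr at 0.40 and Tie1 at 0.38 against Vwf at -0.61 (another probe set -0.20), and that list did not pass (adjusted p = 0.264). In all, 649 lung probe sets passed, 336 higher in A/J and 313 higher in C57BL/6J, and 39 differed at least 2-fold. In the same order, 153 and 206 passed with time 1 alone and 280 and 162 with time 2 alone. All 649 had the same sign at both times, which the test favours, and over all probe sets the differences at the 2 times correlated at 0.297.

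Some strain differences were shared by all tissues. Gas5 was higher in C57BL/6J by 3.02 in liver, 2.75 in heart, 3.47 in spleen and 2.96 in lung, Ctsc by 1.85, 1.09, 2.14 and 2.53, and Snhg6, another non-coding host of small nucleolar RNAs, by 1.65, 1.96, 1.80 and 1.38. Glo1 was higher in A/J by 1.24, 1.63, 1.99 and 1.79, with its other probe set at 1.23, 1.52, 1.65 and 1.62, and Alad by 1.05, 1.195, 3.06 and 1.09. Spg21, Hopx, Qsox1, Thumpd1 and Rps4l were higher in C57BL/6J in all 4 tissues, and H2-D1, Mtm1, Gnb1, Cap1, Ssr1 and Gatm in A/J. Other probe sets of several of these genes showed little or no such difference. In liver that of Snhg6 gave 0.06, that of Ssr1 -0.03, that of Mtm1 -0.02 and that of Rps4l 0.13, and none of these 4 passed in any tissue. For Gas5, 1 lay between -0.08 and 0.08, while the other was called in the same direction in heart (-0.25) and spleen (-0.52) but not in liver (-0.11) or lung (-0.24). For Ctsc, 1 was called in the same direction in all 4 tissues (-0.40, -0.30, -0.49 and -0.64), and the other gave -0.16, 0.19 and 0.04 and was called in the opposite direction in lung (0.68). Those of H2-D1 gave -0.25 and -0.12 in liver, the first called in the opposite direction in heart (-0.57). For Qsox1, 1 was called at -0.39 in liver and in the opposite direction at 0.38 in spleen, and for Gnb1 both were called in the same direction in 2 tissues. Of 12422 probe sets, 2810 passed for strain in at least 1 tissue and 53 in all 4, where independent lists would give 0.251. Of the 53, 51 had 1 direction, 17 higher in A/J and 34 higher in C57BL/6J, from 41 named genes. Of 624 called in 2 or more tissues, 137 had opposite directions. Pairs of tissues shared between 119 calls (liver and lung, 26.4 expected) and 275 (heart and spleen, 118 expected), and the share with the same direction ran from 78.9% to 95.8%.

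**Figure D2:**
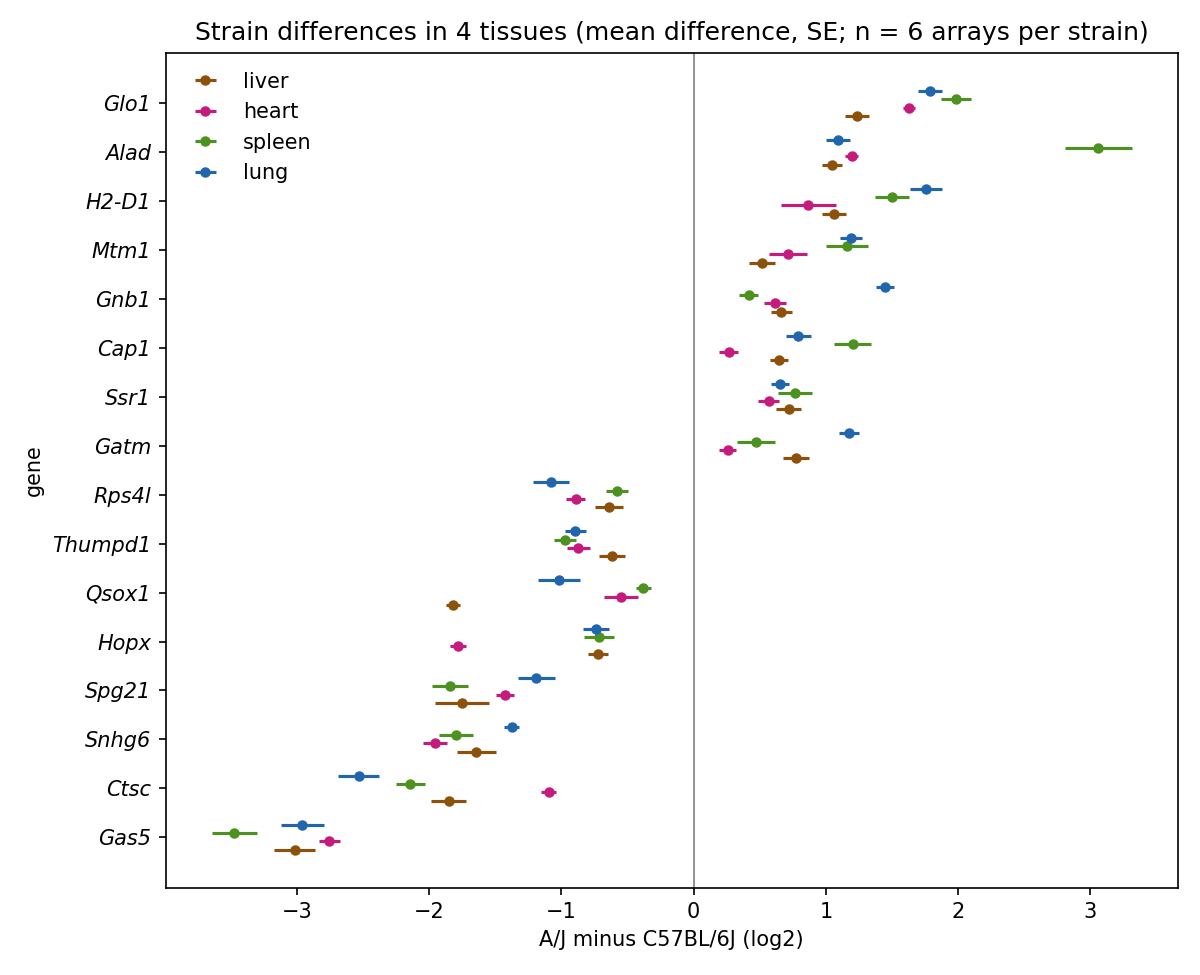
A/J minus C57BL/6J difference (horizontal, log2) with its SE for the 16 named genes (vertical) called in all 4 tissues, by tissue (colour), n = 6 arrays per strain. Gas5 lies between -3.47 and -2.75 and Glo1 between 1.24 and 1.99.

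Genes with known alleles in these strains were read in every tissue, passed or not. Hc was lower in A/J in liver (-2.18, SE 0.08) and lung (-0.64, SE 0.13), and did not pass in heart (-0.12) or spleen (0.04). H2-Ea, whose product is missing from C57BL/6 mice, was higher in A/J in spleen (1.04, SE 0.12). Ahr, the aryl hydrocarbon receptor, was higher in A/J in lung (0.78, SE 0.11) and stood at -0.54 in liver with adjusted p = 0.0621. Il3ra passed in no tissue by limma, with values from -0.11 to 0.09. Nnt, the mitochondrial transhydrogenase, part of which is deleted in C57BL/6J, was higher in A/J in liver (0.82, SE 0.14). It did not pass for strain in heart (0.33, adjusted p = 0.108), spleen (0.25, adjusted p = 0.174) or lung (0.40, adjusted p = 0.0988). At time 1 its A/J minus C57BL/6J difference was 0.36 in liver, -0.02 in heart, -0.08 in spleen and -0.02 in lung, and at time 2 it was 1.28, 0.67, 0.58 and 0.81. The list of 6 measured alleles passed in spleen (2 higher, 2 adjusted over the list alone; adjusted p = 0.00267, and adjusted p = 0.0844 with an estimated correlation) and in lung (2 higher and 1 lower, 4 and 1 adjusted over the list alone; adjusted p = 0.00919, and adjusted p = 0.484 with an estimated correlation).

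**Figure D3:**
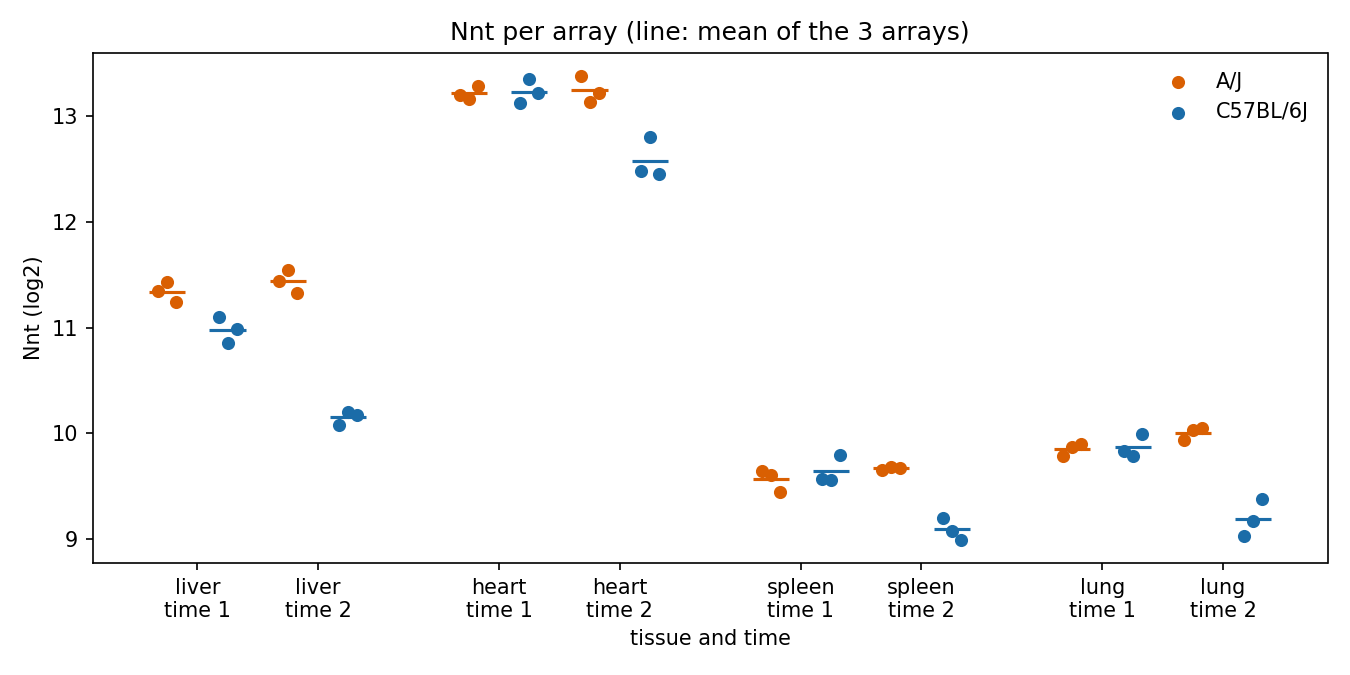
Nnt level (vertical, log2) in each array by tissue and time (horizontal) and strain (colour), with the mean of the 3 arrays of each group as a line. In every tissue the 3 C57BL/6J arrays at time 2 lie below all other arrays, with a mean of 10.15 in liver against 10.98 at time 1.

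Whether strain differences themselves differed between tissues was asked by the strain by tissue test. Cyp2c39 was higher in A/J by 2.67 in liver (SE 0.07) and by 0.02 to 0.10 elsewhere. Nnmt (-2.52), Asl (-2.73), Psen2 (-1.94) and Fga (-2.56) were lower in A/J in liver, with values from -0.38 to 0.50 in the other tissues, and Hc was lower in liver (-2.18) and lung (-0.64). Ifi204 was higher in A/J in lung by at least 2.67 and stood at -0.51 in spleen. Baiap2l1 was higher in heart (1.94) and lung (1.86) and stood at -0.28 in liver. Ly6d had a difference of -2.24 in spleen. Cyfip2 had -1.97 in heart, 1700097N02Rik had 1.16 in spleen (C57BL/6J at 10.22, within the 9.99 to 10.32 of the other tissues), and Pttg1 had -1.54 in heart and 0.48 in spleen. The adjusted p of these 12 genes ran from 1.62e-25 (Nnmt) to 3.17e-15 (Fga), with n = 6 arrays per strain and tissue. In all, 2292 probe sets passed, 18.4% of those tested, and 1869 of them had also passed for strain in at least 1 tissue.

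Tissue comparisons, averaged over strains and times, gave the transcripts typical of each organ. The liver transcripts were led by Ambp, which was 93.8-fold above the nearest tissue (13.69 ± 0.12 against 7.14 ± 0.76 in lung, n = 12). Next in liver were F2, prothrombin (6.54 log2 units), Apoh (6.26), Bhmt (6.12), Cfi (5.88), Cyp3a25 (5.86), Plg, plasminogen (5.85), and Mug1 (5.79). Those of heart were led by Myl3, a ventricular myosin light chain, at 14.34 ± 0.02 against 6.98 ± 1.16 in lung (n = 12). It was followed by Myl2 (6.42), Ckmt2 (5.63), Cox7a1 (5.50), Fabp3 (5.25), Ryr2, the calcium release channel (5.05), Nppb (4.995) and Mb, myoglobin (4.98). Spleen was led by Coch at 10.29 ± 0.30 against 5.64 ± 0.21 in heart (n = 12). Also typical of spleen were the antibody genes Igkv1-133 (4.53), Ighg3 (4.46), Jchain (4.26), Igkv6-14 (4.21) and Igkv4-70 (3.97), the B cell protein Cd72 (3.99) and Hemgn (4.02). Lung was led by Chil1 at 11.08 ± 0.42 against 5.57 ± 0.15 in liver (n = 12). Also typical of lung were the surfactant proteins Sftpc (5.01) and Sftpb (3.70), Wfdc2 (4.77), Slc34a2 (4.07), the keratins Krt19 (4.04) and Krt7 (3.93), and Scgb1a1 (3.63). Sftpc and Scgb1a1 each stood at the shared highest value of the array in 3 of the 6 lung arrays of time 1, so their differences are lower bounds, as are differences from tissues near background.

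Marker lists followed the organs. All 15 measured hepatocyte markers were enriched in liver (median level 13.23 against 8.25 in the other tissues), and 15 of 17 cardiomyocyte markers in heart (13.13 against 8.68). So were 12 of 13 B cell markers in spleen (11.70 against 9.18) and 4 of 9 lung epithelium markers in lung (13.84 against 10.34). Endothelial markers were enriched in lung in 6 of 11, and erythroid markers in spleen in 5 of 9. The counts of enriched probe sets were 473 in liver, 329 in heart, 423 in spleen and 265 in lung. Enriched probe sets passed for strain in their own tissue more often than the others did, in liver 17.97% against 3.515%, in heart 24.92% against 7.004%, in spleen 50.35% against 11.39% and in lung 21.13% against 4.878% (Fisher's exact test, p = 1.61e-32, 3.21e-23, 3.88e-82 and 8.37e-20, where probe sets are not independent). The others include dim probe sets that can show less, so this excess cannot be told apart from one of signal level.

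Time 2 was compared with time 1 within each tissue, a split that is also one of array runs. In liver, genes of sterol synthesis were higher at time 2: Msmo1, a sterol oxidase, was 3.48-fold higher (10.16 ± 0.34 against 8.36 ± 0.19, n = 6 per time), and Idi1 rose by 1.80, Hmgcs1 by 1.44 and Fdps by 1.303. Cyp2b10, a cytochrome P450, was 3.89-fold higher (12.16 ± 0.56 against 10.20 ± 0.34, n = 6). Acot1, a thioesterase of fatty acids, fell by 1.51 (SE 0.29) and Ehhadh, of peroxisomal oxidation, by 1.07 (SE 0.25). The change was -2.49 in A/J and -0.53 in C57BL/6J for Acot1, and -1.86 and -0.29 for Ehhadh. Of 17 cholesterol synthesis genes 13 rose (13 adjusted over the list alone), with adjusted p = 1.11e-08 and adjusted p = 0.283 with an estimated correlation. Of 15 fatty acid synthesis genes 10 rose and 2 fell (the same adjusted over the list alone), with Acly at 1.02 and Fasn at 0.62, adjusted p = 0.00729 and adjusted p = 0.242 with an estimated correlation. Other liver genes named by the rule were 1110032A03Rik (3.91, SE 0.12), Mrm3 (2.36), Anp32a (2.31), Dynll2 (1.89), Tbcel (-1.56), Kap (-1.42), Dusp6 (-1.12) and Tgfbi (-1.11).

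The remaining liver lists past the test were, with genes up and down, complement and coagulation (14 and 2 of 25; 15 and 2 adjusted over the list alone; adjusted p = 5.95e-04, and adjusted p = 0.332 with an estimated correlation), and glutathione and NRF2 genes (15 and 3 of 32; 19 and 3 adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.332 with an estimated correlation). Oxidative phosphorylation (29 and 7 of 57, 32 and 7 adjusted over the list alone) had adjusted p = 1.29e-04 and adjusted p = 0.566 with an estimated correlation. Male-biased liver genes (6 and 0 of 12, 6 and 0 adjusted over the list alone) had adjusted p = 0.00901 and adjusted p = 0.309 with an estimated correlation, with Hsd3b5 at 1.49 and Elovl3 at 0.71. Cytochrome P450 genes (8 and 2 of 22, the same adjusted over the list alone) had adjusted p = 0.0106 and adjusted p = 0.283 with an estimated correlation. Hepatocyte markers (6 and 1 of 15, the same adjusted over the list alone) had adjusted p = 0.026 and adjusted p = 0.566 with an estimated correlation, with Ttr, transthyretin, at 1.47. The median of this list was 0.08, and -0.0043 with quantile normalization. Acute phase genes (8 and 2 of 21, 8 and 1 adjusted over the list alone) had adjusted p = 0.0318 and adjusted p = 0.563 with an estimated correlation, with Apcs at 1.00 and Orm1 at 0.66. Interferon response genes (9 and 1 of 22, 8 and 1 adjusted over the list alone) and B cell markers (0 and 9 of 13, the same adjusted over the list alone) each had adjusted p = 0.0443, and adjusted p = 0.632 and 0.566 with an estimated correlation. The interferon list no longer passed with the mean over all probe sets of each gene (adjusted p = 0.103). With quantile normalization the medians of all these liver lists shrank. That of oxidative phosphorylation went from 0.19 to 0.058, that of glutathione and NRF2 genes from 0.23 to 0.12, and that of complement and coagulation from 0.28 to 0.16. Time differences in liver also correlated with mean level over all probe sets (0.281), and the cause was not tested. Probe sets of Alb, Apoa1, Hp, Kng1, Mup3 and Serpina1e stood at the shared highest value in 5 or 6 livers of time 1. A rise of these list members at time 2 can thus be overstated.

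In lung, transcripts of the liver were lower at time 2. Alb fell by 3.35 (12.30 ± 1.19 against 8.95 ± 0.59, n = 6 per time), and Serpina1c by 2.66, Mup3 by 2.46, Bhmt by 2.40, Cyp4a10 by 2.21 and Serpina1e by 2.09. All 15 hepatocyte markers fell (15 adjusted over the list alone), with Apoa1 at -1.83 and Ahsg at -1.18, adjusted p = 3.75e-07 and adjusted p = 0.742 with an estimated correlation. Complement and coagulation genes fell in 9 of 25 and rose in 2 (10 and 2 adjusted over the list alone), with Plg at -1.19, adjusted p = 0.0283 and adjusted p = 0.742 with an estimated correlation. Higher at time 2 in lung were Anp32a (2.104, SE 0.16), Pcsk5, a proprotein convertase (1.53, SE 0.09), Dynll2 (1.51), 1110032A03Rik (1.48), Clec3b (1.40) and Map3k3 (1.39). The 3' minus 5' difference of the Gapdh control went from 0.83 ± 0.15 to 1.62 ± 0.31 in the A/J lungs and from 0.90 ± 0.23 to 1.26 ± 0.18 in the C57BL/6J lungs (n = 3).

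In spleen, liver transcripts were higher at time 2, with Alb up by 2.05 (SE 0.55), by 3.76 in A/J and by 0.33 in C57BL/6J, and Serpina1c (2.35, with 3.58 in A/J and 1.13 in C57BL/6J), Mup3 (2.11) and Serpina1e (1.82) likewise. Hepatocyte markers rose in 10 of 15 (12 adjusted over the list alone), with Ambp at 1.46, adjusted p = 3.3e-05 and adjusted p = 0.66 with an estimated correlation. Oxidative phosphorylation genes rose in 28 of 57 and fell in 2 (31 and 2 adjusted over the list alone), with Cox7a1 at 0.68, adjusted p = 1.18e-07 and adjusted p = 0.504 with an estimated correlation. Immediate early genes rose in 11 of 26 and fell in 1 (the same adjusted over the list alone), with Junb at 0.59 and Gadd45b at 0.54, adjusted p = 0.00401 and adjusted p = 0.504 with an estimated correlation. MHC and antigen processing genes rose in 7 of 20 and fell in 2 (9 and 3 adjusted over the list alone), with H2-Ea at 0.73 and Psmb9 at 0.63, adjusted p = 0.0212 and adjusted p = 0.504 with an estimated correlation. Of this list, Cd74 stood at the shared highest value in 5 of the 6 spleens of time 1. Further genes were Cotl1 (2.41, SE 0.15), Anp32a (2.102, SE 0.07), Ywhaq (-1.38), Odf2 (-1.17), Vamp3 (-1.03), Adipoq (-1.003), Zfp617 (-0.97) and Actb, a cytoplasmic actin (-0.92, with -0.11 in A/J and -1.73 in C57BL/6J).

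In heart, Mapkapk2, a stress kinase, was 3.40-fold higher at time 2 (10.43 ± 0.18 against 8.67 ± 1.06, n = 6 per time), followed by Pcsk5 (1.40), Nfix (1.38), Wnk1 (1.296), Dynll2 (1.17) and Anp32a (1.16). Scgb1a1 fell by 2.21 (SE 0.59), Mt2, a metallothionein, by 1.07 (SE 0.15), Zscan12 by 1.03, Zbtb16 by 1.01 (-1.72 in A/J and -0.29 in C57BL/6J), Acot1 by 0.98 and Alb by 0.96. With camera, 0 of the 37 lists passed for time in heart, where 3 had an unadjusted p under 0.05 and 7 passed with fry. The circadian clock list passed for time in no tissue (18 genes measured; in liver 3 rose and 3 fell, and 3 and 3 adjusted over the list alone). In liver its median was -0.04 and its mean 0.03. Camera asks for a shift of a list in 1 direction, so genes that rise and genes that fall cancel. A difference of the clock between the times is therefore not excluded. The counts past the test were 6248 in liver (2512 higher at time 2), 4341 in heart (1945), 3962 in spleen (1615) and 4312 in lung (1960). Without the 5 spleen arrays named above the spleen count was 226, 224 of them shared in the same direction, where leaving out other sets of 5 arrays of the same layout gave a median of 438.5, and in lung 586 passed in C57BL/6J alone. In all 4 tissues 737 passed, 679 in 1 direction, where independent lists would give 241.7 in all 4.

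**Figure D4:**
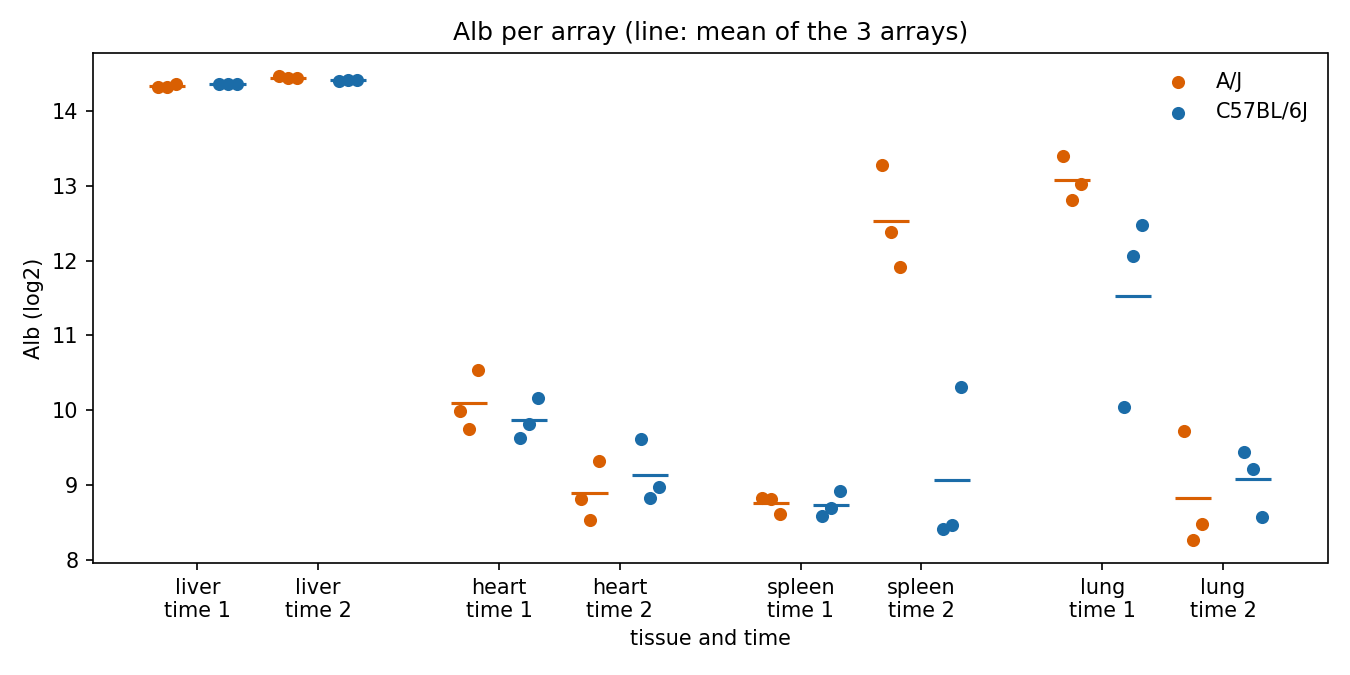
Alb level (vertical, log2) in each array by tissue and time (horizontal) and strain (colour), with the mean of the 3 arrays of each group as a line. Outside liver the highest group means are lung at time 1, at 13.07 in A/J and 11.53 in C57BL/6J, and A/J spleen at time 2, at 12.52.

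The strain by time test asked whether the strain difference at time 2 departed from that at time 1. In liver the A/J minus C57BL/6J difference of Cyp2b9 was 0.60 at time 1 and 3.38 at time 2 (n = 3 per group, adjusted p = 1.23e-05), both of them lower bounds, as the C57BL/6J livers stood at the level of the other tissues. Hsp90aa1, a heat shock protein, went from 0.54 to -0.92, Rhpn2 from 0.62 to -0.9985, and Lpin2, a phosphatidate phosphatase, from 0.10 to -1.42. In heart Rab4a went from -0.23 to 0.69, Eif4ebp1, a repressor of translation, from 0.51 to -0.61, Rab6a from -0.84 to 0.29, and Ranbp9 from 0.74 to -0.33. In spleen Mki67 went from 0.96 to 3.53, Cmas from 0.18 to 1.65, Piga from 0.72 to 2.02, and Abcg2, a transporter of red cell precursors among others, from 0.66 to 2.22. In lung Npr3, the clearance receptor of natriuretic peptides, went from 0.85 to -0.36, Lox, lysyl oxidase, from 0.84 to -0.43, F3, tissue factor, from 0.55 to -0.21, and the chemokine receptor Cxcr4 from -0.10 to 1.13. Probe sets past the test numbered 609 in liver (125 with a larger value at time 2 and 484 with a smaller one), 48 in heart, 26 in spleen and 22 in lung. These counts moved with single arrays, the liver count between 229 (without A/J time 1 replicate 2) and 1213 (without A/J time 2 replicate 2), and the spleen count between 0 (without A/J time 1 replicate 3, where limma gave 1957 at an unadjusted p under 0.05) and 337 (without A/J time 2 replicate 1). The heart count ran from 25 (without C57BL/6J time 1 replicate 1) to 102 (without A/J time 1 replicate 2) and was 7 without the 2 A/J hearts of time 1 with a high Gapdh 3' end, and the lung count from 4 (without A/J time 1 replicate 1) to 91 (without A/J time 2 replicate 3).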

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

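The tests of liver RNA, of array runs, of Nnt and of probe sequences were chosen only after the result they bear on was seen, and the counts over other splits of the samples were planned.

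Strain differences differed between tissues by the strain by tissue test for 2292 probe sets, and 196 of the 379 probe sets named by the strain rule were among them. The highest count among 99 other drawn splits was 819, so chance dealing of the strain labels can be excluded (1 of 100 splits as large, the real one). The range over the 4 tissues of the A/J minus C57BL/6J difference was 3.19 for Ifi204 (a lower bound, as the C57BL/6J lungs at 8.04 stood no higher than the other tissues), 3.06 for Fga, 2.78 for Asl, 2.65 for Cyp2c39, 2.40 for Nnmt, 2.22 for Ly6d, 2.22 for Baiap2l1, 2.22 for Hc, 2.09 for Cyfip2, 2.02 for Pttg1, 2.02 for Psen2 and 1.195 for 1700097N02Rik.

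Strain differences also differed between the times, by the strain by time test, for 609 probe sets in liver, 48 in heart, 26 in spleen and 22 in lung. Over 82 splits of each tissue's 12 arrays, the real one included, the highest other counts were 1 in liver, 1 in heart and 2 in lung. Chance dealing of single arrays can thus be excluded there (1 split as large, the real one), but not chance differences between litters. In spleen 2 splits were as large, the real one and another that gave 133, several times the real count. That rank met the planned limit, but with such a split among the others chance is not excluded in spleen. What that split separates was not tested. The change of the strain difference from time 1 to time 2 in liver was 2.78 for Cyp2b9 (not exact, as the C57BL/6J livers stood at the level of the other tissues), -1.46 for Hsp90aa1, -1.62 for Rhpn2 and -1.52 for Lpin2, and in heart 0.93 for Rab4a, -1.12 for Eif4ebp1, 1.13 for Rab6a and -1.07 for Ranbp9. In spleen it was 1.47 for Cmas, 2.57 for Mki67, 1.29 for Piga and 1.56 for Abcg2, and in lung -1.21 for Npr3, -1.27 for Lox, -0.77 for F3 and 1.23 for Cxcr4.

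Hepatocyte transcripts stood out in lung at time 1 and in A/J spleen at time 2, with Alb at 13.07 and 11.53 in the lungs of A/J and C57BL/6J at time 1, 12.52 in the A/J spleens at time 2, and 14.33 to 14.44 in liver. RNA of liver may account for the lung values, since 76.67% of 90 probe sets abundant in liver (mean above 13 and at least 3 above heart) were called higher at time 1 there, against 18.51% of the other probe sets. In spleen a first test, that most of these 90 be at least 1 log2 unit higher in A/J at time 2, was not met, at 25.56% against 1.046% of the other probe sets (the same limit gave 31.11% in lung), and a later one gave a Spearman correlation across the 90 probe sets, which are not independent replicates, of 0.6845 between the strain by time difference in spleen and the excess in lung, so liver RNA stays open there too. A difference between array runs would move both strains of spleen alike. The mean of the hepatocyte markers went from 7.915 to 8.828 (8.529 to 9.246 over 3 arrays) in A/J. In C57BL/6J it went from 7.785 to 8.04 (7.865 to 8.333). These values argue against runs as the whole account in spleen, whereas in lung run and time cannot be told apart. Of 15 hepatocyte markers, 14 had a strain by time difference above 0. That count restates the pattern, as the markers move together, and adds no evidence. It was chosen after medians of 0.42 over the 90 and 0.52 over the 15 had settled nothing against a bound of 0.5. A biological difference between the animals of the 2 times stays open and untested.

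Nnt was lower in C57BL/6J at time 2 than in any other array of the same tissue, and its strain by time difference was 0.92 in liver, 0.69 in heart, 0.66 in spleen and 0.83 in lung, with limma adjusted p of 0.00172, 0.0559, 0.0594 and 0.0176 over all probe sets and 1.1e-05, 2.4e-04, 2.4e-04 and 3.68e-05 over the 4 tissues (n = 3 per group). A difference between array runs would move both strains alike, but the smallest of these differences was 0.6567, while A/J changed by 0.033 to 0.15 and C57BL/6J fell by 0.55 to 0.83. Swapped labels of the C57BL/6J samples at time 1 would leave no strain difference at that time. Over the probe sets called in all 4 tissues its median size was 0.5553 at time 1 and 0.6124 at time 2. Calling them used the time 1 arrays, which favours a difference there. Over all probe sets, called or not, the differences at the 2 times correlated at 0.187 in liver, 0.477 in heart, 0.452 in spleen and 0.297 in lung. With time 1 alone 344, 438, 603 and 359 passed for strain in the same order. These values argue against such a swap. A candidate explanation is that the C57BL/6J animals of time 1 and time 2 came from stocks or litters that differ at Nnt, which was not tested. The 4 tissues may come from the same animals, so they are not independent evidence.

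The strain calls shared by all 4 tissues leaned to C57BL/6J, with 66.67% higher there against 44.1% of the 2186 probe sets called in 1 tissue (Fisher's exact test, p = 0.00157; probe sets are not independent). Whether strain variants in the probed sequence account for part of them was asked of 27 other probe sets of 18 of these genes, of which 22.22%, or 6, were called in the same direction in at least 1 tissue and 5 in the opposite one. That share is too low, because it left out the other probe sets of Glo1 and Ctsc that were themselves called in all 4 tissues, and with them, in a later count, it was 27.59%, or 8 of 29. It decides nothing here, as some of the other probe sets are dim, such as 1 of Gas5 and that of Snhg6 with mean levels of 5.72 and 5.63, and could miss a real difference. Sequence variants and a difference in expression between the strains both stay open, as the probe sequences were not used here.

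The 9 probe sets of the hybridization controls, spiked-in transcripts left out of all comparisons, were higher at time 2 by 3.12 in liver, 3.35 in heart, 3.14 in spleen and 3.24 in lung (n = 6 arrays per time), a signal in data that the report does not use.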

How the results depend on the processing

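The 5 spleen arrays, the 2 heart arrays and the probe sets of other tissues were left out only after the data were seen. Of the values of named genes under the alternatives, 25665 kept their side of the threshold, 451 came to pass it, 1900 no longer passed it and 8 reversed. A change of sign counted as reversed only where at least 1 of the 2 fits passed. The 25665 may therefore hold changes of sign in values that passed in neither fit. Those 8 are time differences: with A/J alone Prss2 (-0.29) and Nnt (0.094) in liver, Nnt in heart (0.033) and Car2 in spleen (0.40), and with quantile normalization Ager in lung (-0.017). The others reversed without the liver array C57BL/6J time 2 replicate 2, the one with the highest pancreas markers of the liver. Over single arrays left out they ran from -0.35 to 1.07 for Prss2, -0.15 to 0.72 for Pnliprp1 and -0.22 to 0.55 for Cel, lowest without that array and highest without replicate 3 of its group. Total counts of calls not named here stayed within 1.5 times of those reported, under each alternative run for them, but counts by direction moved more. With time 1 alone those higher in C57BL/6J were 143 in liver, and with time 2 alone 445 in spleen and 162 in lung. Without the 4141 dimmest probe sets those lower at time 2 were 2264 in liver and 1419 in spleen. Strain by time differences above 0 were 14 in heart with quantile normalization, and those below 0 were 10 in spleen without the 5 arrays. Without the time term 197 strain calls passed in liver, 450 in heart, 985 in spleen and 323 in lung. With time 1 alone they were 438 in heart, 603 in spleen and 359 in lung, and strain by tissue 1217. With time 2 alone 500 passed in heart, all from fewer arrays, but 1260 in liver. With 1 fit of all 48 arrays 963 passed in liver, 2686 in spleen and 1097 in lung, and with array weights 1037 in lung. Without the 5 spleen arrays 358 passed for strain and 226 for time, where other choices of 5 arrays of the same layout gave medians of 322 and 438.5. Without the 2 A/J hearts of time 1 with a high Gapdh 3' end, 7 passed for strain by time in heart, from fewer arrays. Time calls in A/J alone were 3427 in liver and 2363 in heart, and in C57BL/6J alone 1616 in heart, 1027 in spleen and 586 in lung. Signal near background limits what dim probe sets can show, and without those 4141 the strain by time counts were 83 in heart and 7 in lung, and with quantile normalization 12 in spleen. A limit of 2 log2 units gave 256 enriched in liver, 107 in heart, 136 in spleen and 58 in lung. Of 46 list calls 0 held in camera with an estimated correlation (17 of 296 at an unadjusted p under 0.05; 76 passed with fry), and 49 passed with the mean of all probe sets, with 4 calls lost and 7 gained. For strain in liver 4 of 7 lists then passed, for strain in heart 9 against 6, and for strain in lung 6 against 4. In 1 of the 46, hepatocyte markers for time in liver, the median changed sign with quantile normalization. In the other liver lists for time it shrank. Where no reason is given, the cause was not tested.

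No steady pairing by replicate number was seen, though groups of 3 arrays cannot exclude one. Over 24 pairs across strains the residuals correlated from -0.58 to 0.36 (median -0.03), and over 72 pairs across tissues the median was 0.02. With the numbers as a block, strain gave 276, 756, 1137 and 577 calls in liver, heart, spleen and lung, and time 5611, 3772, 3074 and 4266. Strain by time gave 319, 58, 6 and 25, strain by tissue 2245, and enrichment 473, 329, 423 and 265.

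Leaving out each array in turn gave 361 to 543 strain calls in liver, 715 to 915 in heart, 1193 to 1596 in spleen and 468 to 874 in lung, and 5458 to 6603, 3767 to 4092, 3091 to 4448 and 3455 to 5308 time calls. Strain by tissue ran from 2125 to 2550, and enrichment from 467 to 480 in liver, 320 to 330 in heart, 414 to 431 in spleen and 259 to 272 in lung. Strain by time counts moved by over 1.5 times with single arrays. In liver they were 248 and 229 without A/J time 1 replicates 1 and 2, 234, 1213 and 291 without A/J time 2 replicates 1, 2 and 3. They were 369 without C57BL/6J time 1 replicate 3, and 387 and 373 without C57BL/6J time 2 replicates 1 and 3. In heart they were 27 and 102 without A/J time 1 replicates 1 and 2, 26 without A/J time 2 replicate 3. For C57BL/6J they were 25, 81 and 26 without C57BL/6J time 1 replicates 1, 2 and 3, and 29 without C57BL/6J time 2 replicate 1. In spleen they were 1, 13 and 0 without A/J time 1 replicates 1, 2 and 3 (for the last limma gave 1957 at an unadjusted p under 0.05), 337 and 11 without A/J time 2 replicates 1 and 2. For C57BL/6J they were 3, 129 and 2 without C57BL/6J time 1 replicates 1, 2 and 3, and 5, 81 and 223 without C57BL/6J time 2 replicates 1, 2 and 3. In lung they were 4, 40 and 12 without A/J time 1 replicates 1, 2 and 3, and 91 without A/J time 2 replicate 3. For C57BL/6J they were 54 without C57BL/6J time 1 replicate 2, and 40 without C57BL/6J time 2 replicate 1.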

Other observations

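The strain by time tests of gene lists, the omission of 2 hearts and the search for probe sets that moved in all 4 tissues were chosen only after the data were seen, and the genes named with them were chosen after their values were seen. The other tests here were planned or their outcome was written down before the result.

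In liver, fatty acid oxidation had the most genes past the strain by time test among the 37 lists, 20 of 29 measured, all with a smaller A/J minus C57BL/6J difference at time 2 (camera adjusted p = 7.06e-17, and adjusted p = 0.226 with an estimated correlation). Their median difference was 0.21 at time 1 and -0.43 at time 2, and their median change from time 1 to time 2 was -0.54 in A/J and 0.13 in C57BL/6J. The mean of the hepatocyte markers went from 12.90 to 12.98 in A/J and from 13.01 to 13.33 in C57BL/6J, so cell content is not excluded. Acot1 went from 0.92 to -1.04, and Ppara, the nuclear receptor of fatty acids, from 0.79 to -0.27. Acadm, a dehydrogenase of medium chain fatty acids, went from 0.32 to -0.50, and Cpt2, of the carnitine shuttle, from 0.21 to -0.60 (n = 3 per group). Heat shock genes moved likewise in 8 of 19 (adjusted p = 6.24e-06, and adjusted p = 0.226 with an estimated correlation), with Hspa8 from 0.20 to -1.28 and Hspa1b from 0.30 to -1.44. Genes of the ER stress response did so in 5 of 20 (adjusted p = 5.88e-04, and adjusted p = 0.315 with an estimated correlation), with Hspa5, the chaperone BiP, from 0.25 to -0.82 and Herpud1 from 0.15 to -0.87. From time 1 to time 2 Hspa5 changed by -0.16 in A/J and 0.90 in C57BL/6J, and Herpud1 by -0.31 and 0.71. Of the C57BL/6J livers of time 2, replicate 2 had high pancreas markers (mean 12.90), and these lists are not given without it here.

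The median difference of 20 MHC and antigen processing genes was -0.23 at time 1 and 0.15 at time 2 in liver (strain by time adjusted p = 1.62e-04, and adjusted p = 0.302 with an estimated correlation). It was -0.32 and -0.06 in heart (adjusted p = 5.36e-08, and 0.368 with an estimated correlation) and -0.36 and 0.18 in lung (adjusted p = 3.87e-12, and 0.46 with an estimated correlation). In the lungs the mean of the B cell markers went from 9.16 to 9.57 in A/J and from 9.39 to 9.21 in C57BL/6J, and the Gapdh 3' minus 5' end from 0.83 to 1.62 and from 0.90 to 1.26 (n = 3), so neither cell content nor RNA quality is excluded there. In the hearts the mean of the lung epithelium markers went from 9.765 to 9.561 in A/J and from 10.52 to 9.959 in C57BL/6J. Whether this bears on the MHC list was not tested. The A/J hearts of time 1 stood apart in the Gapdh control (0.95 for its 3' minus 5' end, against 0.096 to 0.26). Without the 2 highest of them the heart medians were -0.27 and -0.06 (adjusted p = 2.84e-04, and 0.501 with an estimated correlation), and the interferon list no longer passed there (adjusted p = 0.0955). In spleen it was -0.26 and -0.31, and the list did not pass (adjusted p = 0.288). By limma 2 of these genes passed in liver, 1 in lung, and 0 in heart and spleen, where 10 and 5 had an unadjusted p under 0.05. Of 22 interferon response genes 0 passed by limma in any tissue, while 3 in liver, 6 in heart, 9 in spleen and 10 in lung had an unadjusted p under 0.05. Their medians were -0.25 and -0.09 in liver, where the list did not pass (adjusted p = 0.0583), -0.25 and -0.05 in heart (adjusted p = 0.0116, and 0.679 with an estimated correlation), -0.42 and -0.03 in spleen (1.02e-07 and 0.25) and -0.22 and 0.06 in lung (5.79e-05 and 0.518). In all 4 tissues 9 probe sets had a strain by time p under 0.05 with 1 sign, where independent tissues would give 1.4. Among them were H2-Ab1, an MHC class II gene (0.48 in liver, 0.33 in heart, 0.37 in spleen and 1.36 in lung), the interferon-induced GTPases Igtp (0.93, 1.03, 0.52 and 1.02) and Irgm2 (0.60, 0.74, 0.54 and 0.76). Others were Npc1, of cholesterol transport (-0.50, -0.70, -0.43 and -0.31), Errfi1 (-0.37, -0.30, -0.94 and -0.61), Erdr1 (-1.66, -1.10, -1.06 and -0.98) and Nnt.

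Erythroid precursors that divide may carry the cell cycle transcripts of spleen. As a test, the deviations of the erythroid and cell cycle list means from their group means were correlated over the 12 spleen arrays, which gave r = 0.8244 (one-sided permutation p = 8e-04) and Spearman's rho = 0.888 (p = 6.3e-04), the only relation tested. Without the 2 arrays farthest from the median r was 0.667. Other dividing cells, and a shared effect of RNA from other organs on both lists, stay open.

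Alleles linked on the chromosome may place strain calls side by side. Neighbouring measured genes were both called 24 times in liver against a mean of 20.8 over 10000 random dealings (permutation p = 0.257), 94 against 69.4 in heart (p = 0.0021), 223 against 188 in spleen (p = 0.0013) and 41 against 31.5 in lung (p = 0.0478). Adjusted over the 4 tissues these p were 0.257, 0.0042, 0.0042 and 0.0637. The smallest ratio was 1.156, in liver. Neighbours whose symbols begin with the same letters were left out, which left 7633 pairs, so families under 1 name do not give this excess. Related genes with unlike symbols that lie side by side and share expression could still give it.

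Exocrine pancreas markers had means of 13.06, 12.72, 12.31, 13.18 and 12.08 in 5 spleen arrays (A/J time 1 replicates 1 and 3, C57BL/6J time 1 replicate 2, and C57BL/6J time 2 replicates 1 and 3), and 12.90 in the liver array C57BL/6J time 2 replicate 2, against 9.32 to 9.77 in the other liver arrays. Pancreas RNA in that liver array as the main source of the strain by time calls in liver is argued against, since 428 probe sets passed without it, 391 of them shared in the same direction with the 609 of all arrays. Gapdh, read by control probe sets near both ends, was higher at the 3' end than at the 5' end by 0.25 ± 0.07 in liver, 0.38 ± 0.47 in heart, 0.76 ± 0.22 in spleen and 1.15 ± 0.38 in lung (SD, n = 12). By group it stood apart in the A/J hearts of time 1 (0.95) and was higher at time 2 in lung (1.62 in A/J and 1.26 in C57BL/6J, against 0.83 and 0.90 at time 1). In spleen it was 0.96 and 0.76 in A/J and 0.78 and 0.53 in C57BL/6J at time 1 and time 2 (n = 3).

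Over 100 splits of the arrays, the real one included, none but the real one gave as many calls for strain, time or tissue enrichment. Chance dealing of the labels to single arrays can thus be excluded for the strain and time counts. Chance differences between litters cannot, since these splits deal out single arrays. For strain the real count and the highest other were 505 and 5 in liver, 929 and 13 in heart, 1580 and 633 in spleen, and 649 and 1 in lung. For time they were 6248 and 4390, 4341 and 14, 3962 and 1578, and 4312 and 1581 in the same order. For enrichment they were 473, 329, 423 and 265 against 0 in the other splits by the same limma test. That outcome was close to fixed, since dealing out the tissue labels mixes the organs in each group, so it adds no evidence.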
